A study of Mus musculus with 14 samples.

How the data were processed

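Total RNA was taken from spleens of female BALB/c mice with TRIzol, per the labels' protocols. Each of 14 samples was labelled with Cy5 and hybridised on its own array together with Cy3-labelled Universal Mouse Reference RNA. The groups were untreated (6 arrays), CpG oligodeoxynucleotides at 400 µg for 3 h (4 arrays) and 400 µg of A151 with 400 µg of CpG for 3 h (4 arrays), with no time given for the untreated mice. The A151 plus CpG samples were grouped by their titles and treatment text, although the short source label of these samples names only A151. The series design text calls the samples independent biological replicates, so that p-values refer to the spread between mice as stated there.

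The deposited values are 1 log ratio per probe and array, treated here as log2 of Cy5 over Cy3 on the basis of the dyes per the labels and of the values themselves, which run below and above 0 and are centred near 0. The base of the logarithm is not given in the sources used here. Values up to 9 rule out base 10, while a natural logarithm cannot be ruled out from the values and would make every fold larger than stated. Image analysis, background correction, filters and normalization are not given in the sources used here, and the deposited log2 values were used without further scaling. A probe without a value on an array was left missing, between 209 and 2009 probes per array.

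The labels describe another labelling protocol for the A151 plus CpG arrays than for the others, in the primer and in its amount. They state it for both channels of an array, so the reference was processed in the same way. The experiment numbers in the labels form separate ranges, of which the A151 plus CpG arrays fill their own, 5 untreated arrays another, 2 CpG arrays with 1 untreated array one more, and 2 CpG arrays the last. CpG against untreated was therefore also fitted with the range as a block and within the only range that holds both groups. No such fit was possible for A151 plus CpG, and its arrays cannot be told apart from their batch.

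Gene names came from the platform annotation given for the probes. Of 30305 probes, 23322 had 1 gene, 180 had several and 6803 were not listed. The gene identifiers of 23202 probes matched the RefSeq table, and 0 symbols changed. Probes with several genes or none were tested as probes and not named. The values of all probes of a gene were averaged, which gave 15198 genes, 10089 of them with 1 probe. Genes with at least 3 values in every group were tested, which left 14947 and took out 251. Il12b and Ifnb1 were among the genes to be named in every comparison and were not tested.

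Group means were fitted over all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no covariates), and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. A total of 29 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. For CpG against untreated, 10 of 12 camera calls held with an estimated correlation, and for the other comparisons 0 of 4 each, where 3 lists each had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 15, 21 and 21 lists. For these set tests 0.98% of the values were missing and were filled with the group mean. List scores were compared with 2-sided exact permutation tests, adjusted over the lists.

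The design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 12 largest increases and the 12 largest decreases among called genes whose arrays do not overlap between the groups, up to 4 members of each list with the largest change among those called, in every comparison, called or not, Il6, Il12b, Tnf, Ifng, Ifnb1, Il1b, Il1rn, Il10, Cxcl10, Ccl2, Ccl4, Irf7, Socs1, Socs3, Nfkbia, Tnfaip3, Myd88 and Tlr9, and the 5 highest and 5 lowest genes set apart on the A151 plus CpG arrays. Another gene that the rule names is not reported here.

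Genes counted as induced or repressed by CpG were called with a log2 difference of at least 1 in either direction. The retained share is their mean difference from untreated in A151 plus CpG over that in CpG. It was also computed with genes chosen on other CpG and untreated arrays than those measured (12 fits), and after a lowess calibration (span 0.1) of A151 plus CpG levels on 8773 genes with an unadjusted p over 0.2 and an absolute difference under 0.5 between CpG and untreated. Intervals of shares of genes are exact binomial (Clopper-Pearson, 95%) and those of calibrated shares come from resampling genes, and neither covers the spread between mice. Genes with both probes induced were compared with genes without a CpG change whose probes lay within a distance of 1 log2 unit in CpG level, with at least 5 such genes each and 20000 draws. Overlap with shared untreated arrays was set beside 100 simulations of unchanged groups.

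The fit was tested on simulated data with 200 of 14947 genes changed in 5 runs. For CpG against untreated it recovered 91.0% of 2-fold and 99.6% of 4-fold changes with 3.8% false calls, for A151 plus CpG against untreated 91.2%, 99.0% and 4.9%, and for A151 plus CpG against CpG 86.2%, 99.4% and 4.8%. The simulated data had independent noise and no batch. These rates therefore do not carry over to the real A151 plus CpG comparisons, in which 66.2% (against untreated) and 64.1% (against CpG) of genes were called. The alternatives were centring each array on its median, quantile normalization, other filters on missing values, probes in place of genes, only the arrays compared, a trended robust variance, array weights, other thresholds, the repeat number or the range of experiment numbers as a block, genes chosen on other arrays, the untreated arrays split between comparisons and leaving out each array. Scaling the arrays to one spread, subtracting a running median along probe numbers, requiring all probes of a gene to be called and the calibration were chosen after seeing the data. Tables were handled and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Signal intensities and background were not analysed here, so that genes near background could not be set apart.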

Results

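Spleen RNA from female BALB/c mice was measured on 14 microarrays to ask whether oligodeoxynucleotides with TTAGGG motifs alter the genes that CpG DNA switches on through TLR9, the endosomal receptor for unmethylated CpG DNA. Each array carried the spleen sample in Cy5 and Universal Mouse Reference RNA in Cy3. The samples were 6 untreated spleens, 4 spleens taken 3 h after an intraperitoneal injection of 400 µg of CpG oligodeoxynucleotides, and 4 spleens taken 3 h after 400 µg of A151, the oligodeoxynucleotide with TTAGGG motifs, together with 400 µg of CpG oligodeoxynucleotides. Of 30305 probes, between 28296 and 30096 had a value on an array, and 14947 genes could be tested. Differences between groups are given as log2 units ± SE from the limma fit, over 6 untreated, 4 CpG and 4 A151 plus CpG arrays unless another n is given, and the number of arrays limits their precision.

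Spleen-enriched genes had a median log2 ratio to the reference of 4.05 in untreated, 4.51 in CpG and 3.45 in A151 plus CpG arrays, and 10 of 10 lay above 0 in each group. Genes typical of tissues other than spleen had medians of -0.16, -0.25 and -0.28 over 15 genes, of which 5, 6 and 7 lay above 0, so that the direction of the ratio rests on the dyes in the labels and the spleen genes. Across all probes, the mean Pearson correlation was 0.906 between untreated arrays, 0.922 between CpG arrays and 0.936 between A151 plus CpG arrays. It was 0.845 between untreated and CpG arrays, but 0.554 between untreated and A151 plus CpG arrays and 0.535 between CpG and A151 plus CpG arrays. The SD of the log ratios on an array was 1.01 to 1.12 in the untreated and CpG groups and 1.36 to 1.52 in the A151 plus CpG group. Per the labels, the A151 plus CpG samples were reverse-transcribed with another oligo(dT) primer and carry their own range of experiment numbers, so that this batch and the group cannot be told apart.

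**Figure D1:**
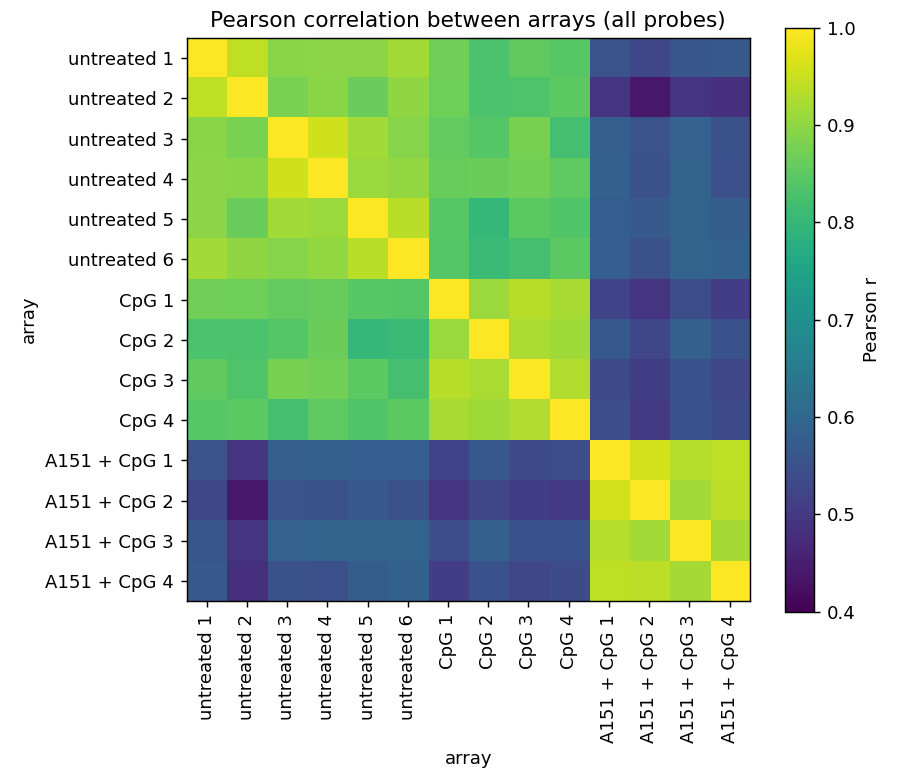
Pearson correlation of the log ratios between each pair of the 14 arrays, over all probes; each row and column is 1 array and the colour scale runs from 0.4 to 1. The A151 plus CpG arrays correlate with each other at 0.917 to 0.960 and with the other arrays at 0.440 to 0.594.

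CpG treatment raised interferon-induced antiviral genes, chemokines and cytokines in the spleen. Ifit2 and Ifit3, antiviral proteins induced by interferon, rose by 4.57 ± 0.19 and 4.44 ± 0.21, and Ifi204, an interferon-inducible DNA-binding protein, rose by 4.46 ± 0.15. The chemokines Ccl12, Cxcl10, Ccl4 and Cxcl11 rose by 4.70 ± 0.27, 4.46 ± 0.20, 4.38 ± 0.13 and 4.22 ± 0.24 (Cxcl11 with 3 untreated arrays). The cytokine genes Il6 and Tnf rose by 3.18 ± 0.26 and 2.25 ± 0.27. Slc40a1, the iron exporter ferroportin of macrophages, fell by 2.66 ± 0.17, and the mesenchymal transcription factor Tcf21 fell by 2.63 ± 0.27. In limma's test, 1768 of 14947 genes differed at an adjusted p under 0.05, 1150 higher and 618 lower, of which 461 and 69 reached 2-fold. Others among the strongest increases were Fpr2 (4.10 ± 0.55), Impg2 (4.07 ± 0.20), Phf11d (4.01 ± 0.16), Usp18 (4.01 ± 0.23), a protease that limits interferon signalling, and Cdh6 (3.96 ± 0.26). Pcdh18 (-2.46 ± 0.25), Id4 (-2.35 ± 0.25), Hpgd (-2.20 ± 0.26), which breaks down prostaglandins, Gpd1 (-2.19 ± 0.20), Arvcf (-1.94 ± 0.21), Cmbl (-1.90 ± 0.19) and Tlx1 (-1.70 ± 0.33), a transcription factor of spleen development, were among the strongest decreases. With the range of experiment numbers as a block, 582 genes passed (469 higher, 113 lower), and within the only range that holds both groups, with 2 CpG arrays and 1 untreated array, 465 passed (386 higher, 79 lower). Both fits rest on that 1 untreated array, which is assumed to vary like the other arrays, and are not separate checks. After quantile normalization the split of the calls was 1326 higher and 1136 lower.

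Type I interferon-stimulated genes rose as a group, with 44 of 48 tested members higher and 0 lower (46 higher adjusted over the list alone; camera adjusted p = 1.62e-67, and 5.54e-05 with an estimated correlation). Of the interferon gamma-inducible GTPases and regulators, 16 of 21 rose (17 adjusted over the list alone; adjusted p = 6.05e-21), among them Gbp2 (3.44 ± 0.14), Cxcl9 (3.15 ± 0.19), Iigp1 (2.99 ± 0.45) and Gbp6 (2.94 ± 0.20). Ifng itself was at 0.05 ± 0.15 (adjusted p = 0.893), a value that turned to -0.16 after quantile normalization. Chemokines had 15 of 25 members higher (16 adjusted over the list alone; adjusted p = 4.8e-16), and cytokines 10 of 30 (11 adjusted over the list alone; adjusted p = 4.71e-06), with Il15 at 1.97 ± 0.24 and Il10 at 1.64 ± 0.23. In the list of NF-kappaB subunits and targets, 17 of 22 rose (20 adjusted over the list alone; adjusted p = 3.91e-21), led by Nfkbiz (3.66 ± 0.18) and Tnfaip3 (2.42 ± 0.15), a brake on NF-kappaB. Negative feedback regulators had 15 of 24 higher (19 adjusted over the list alone; adjusted p = 2.53e-18), with the decoy receptor Il1r2 (3.66 ± 0.25), Socs3 (3.32 ± 0.21) and Socs1 (1.96 ± 0.16). These 6 lists also passed with an estimated correlation. Among the other immune genes followed in every comparison, Il1b (1.15 ± 0.20), Il1rn (1.61 ± 0.16), Ccl2 (1.16 ± 0.14), Nfkbia (1.38 ± 0.20), Myd88 (1.42 ± 0.14) and Tlr9 (0.78 ± 0.16) rose as well. Irf7 was higher by 0.79 ± 0.23 (adjusted p = 0.0284), and lost its call without CpG replicate 1, 3 or 4 (0.123, 0.0511 and 0.0737), without untreated replicate 2 or 6 (0.0543 and 0.0604) and after quantile normalization (0.082).

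**Figure D2:**
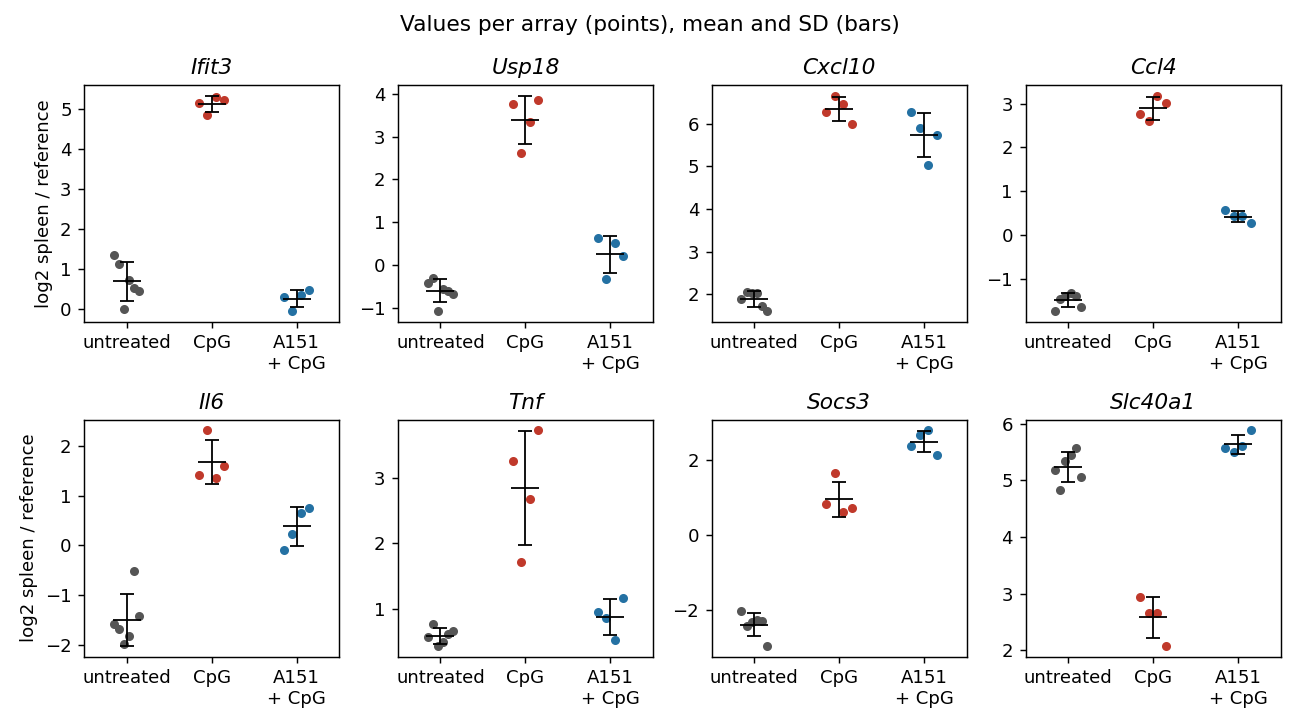
Log2 ratio of spleen to reference for 8 genes on each array (points), with the mean and SD of the 6 untreated, 4 CpG and 4 A151 plus CpG arrays. Ifit3 has means of 0.69, 5.13 and 0.26 in the 3 groups, Cxcl10 of 1.89, 6.35 and 5.73, and Slc40a1 of 5.24, 2.58 and 5.64.

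Acute phase and innate effector genes rose in 16 of 28 members (17 adjusted over the list alone; adjusted p = 1.94e-10), including the metallothionein Mt2 (3.41 ± 0.20), Acod1 (2.72 ± 0.23), which makes itaconate, and Lcn2 (2.64 ± 0.32), which binds siderophores. Co-stimulation and activation markers had 12 of 19 members higher (13 adjusted over the list alone; adjusted p = 1.8e-10), with Cd69 at 2.98 ± 0.24 and Cd274, the ligand of the inhibitory receptor PD-1, at 2.19 ± 0.20. The list named apoptosis, which also holds genes of other forms of cell death, had 11 of 24 members higher (13 adjusted over the list alone, adjusted p = 1.93e-08). Among them were Gadd45b (3.05 ± 0.15), Casp4 (2.97 ± 0.20) and Mlkl (1.87 ± 0.15). MHC class I presentation had 8 of 17 higher (10 adjusted over the list alone; adjusted p = 4.71e-06, and 0.0491 with an estimated correlation), with the peptide transporter gene Tap1 at 1.54 ± 0.19. Immediate early genes had 7 of 24 higher (9 adjusted over the list alone; adjusted p = 0.000552), among them Dusp1 (2.07 ± 0.20) and Myc (1.49 ± 0.14), and the list had an adjusted p = 0.239 with an estimated correlation. In the chemokine, cytokine, negative feedback, immediate early, acute phase and apoptosis lists, 1 member each fell, namely Ccl24, Il7, Pias3, Btg2, Hmox1 and Mcl1, with values from -0.82 ± 0.16 (Il7) to -0.46 ± 0.12 (Mcl1), all named after their values were seen. Of these, Ccl24 lost its call without untreated replicate 1, 2, 3 or 4 or CpG replicate 1, 2 or 4 (adjusted p from 0.0542 to 0.147 in limma's test) and with array weights (0.0639). Hmox1 lost it without untreated replicate 2, 3, 4 or 5 or CpG replicate 2 or 4 (0.0522 to 0.132) and with a trended robust variance (0.0661), and Mcl1 without CpG replicate 1 (0.0619). A running median along probe numbers also ended the calls of Ccl24 (0.0614) and Hmox1 (0.0576).

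Among the cell type lists, neutrophil markers passed, with 7 of 18 higher (7 adjusted over the list alone, camera adjusted p = 0.000498, and 0.0848 with an estimated correlation). Mmp8 (2.86 ± 0.45) and Retnlg (1.64 ± 0.34) were among them. Induced members also included Lcn2 and Chil3 of the acute phase list and Il1r2 of the negative feedback list, so the call does not by itself show more neutrophils. The camera test gave adjusted p = 0.0505 for dendritic cell markers (5 of 18 higher, 1 lower). For TLR9 signalling components it gave 0.0576 (6 of 26 higher, 3 lower, median 0.03), with Cd14 higher by 3.39 ± 0.18 and Tlr2 by 2.00 ± 0.16. It also gave 0.112 for oxidative phosphorylation, 0.135 for T cell markers and 0.262 for B cell markers, of which Cd79b fell by 0.90 ± 0.15. It gave 0.18 for cell cycle, for glycolysis and for pancreatic acinar markers. The values were 0.314 for erythroid markers, 0.38 for MHC class II presentation and for ribosomal proteins, 0.526 for NK cell and cytotoxic markers (Gzmb 2.83 ± 0.30). They were 0.568 for plasma cell markers, 0.787 for platelet and megakaryocyte markers and for heat shock and unfolded protein response, 0.929 for monocyte and macrophage markers and 0.995 for stromal, endothelial and adipose markers. The dendritic cell list passed without CpG replicate 1, 2 or 3 (0.0397, 0.0171 and 0.0486) or untreated replicate 1, 2 or 5 (0.0348, 0.0348 and 0.0481). The TLR9 list passed without CpG replicate 2 or 4 (0.0299 and 0.0429) or untreated replicate 4 or 5 (0.0444 and 0.0481). The dendritic cell and TLR9 lists also passed after scaling to one spread (0.0496 each). The pancreatic list passed as lower without CpG replicate 1 or 3 (0.0103 and 0.00233) or untreated replicate 2 (0.01), and cell cycle without CpG replicate 1 (0.0107) or untreated replicate 5 (0.0481). Oxidative phosphorylation passed as lower without CpG replicate 2 (0.012) or untreated replicate 5 (0.0481), T cell markers without CpG replicate 4 (0.0484) or untreated replicate 5 (0.0481), and erythroid markers without CpG replicate 1 (0.03). The median was below 0 and the mean above it for glycolysis, heat shock and NK cell lists, and for monocyte markers the mean was 0.05, turning to -0.17 after quantile normalization, with camera's direction down. After quantile normalization the lists of B cell (0.00721), T cell (0.014), MHC class II (0.014) and erythroid genes (0.0167) passed as lower.

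On the A151 plus CpG arrays, part of the CpG response was seen against untreated spleen and many genes stood at quite different levels. Socs3, a brake on cytokine signalling, was higher by 4.86 ± 0.21, Cxcl10 by 3.84 ± 0.20, Ccl12 by 3.78 ± 0.27 and Mx2, an interferon-induced antiviral GTPase, by 3.66 ± 0.15. Il6 was higher by 1.89 ± 0.26 and Ccl4 by 1.91 ± 0.13, while Tnf was at 0.28 ± 0.27 (adjusted p = 0.364), a sign that turned after quantile normalization (-0.09) and after scaling the arrays to one spread (-0.04). Spi1, a transcription factor of myeloid and B cells, was lower at -6.13 ± 0.20, the ribosomal protein gene Rpl7a at -5.52 ± 0.18, the immunoglobulin variable segment Ighv2-3 at -5.43 ± 0.24 and the histone genes H4c4, H2ac19, H4c14 and H4f16 at -5.06 to -4.69. In limma's test, 9892 of 14947 genes differed from untreated, 5298 higher and 4594 lower, and 4483 of them reached 2-fold. Different probes of one gene gave unrelated differences here. Across 4899 genes with 2 to 5 probes, the correlation of the first with the second probe was 0.578 for CpG against untreated, 0.037 for A151 plus CpG against untreated and 0.068 for A151 plus CpG against CpG. Of 2463 genes with both probes called against untreated, 48.8% had the same sign (95% exact binomial interval 46.8 to 50.8), against 97.9% of 235 genes for CpG. The levels of the first and second probes had a correlation of 0.617 in untreated, 0.645 in CpG and 0.223 in A151 plus CpG arrays. Genes are not independent replicates in these values. Whether a probe number stands for the same sequence on the A151 plus CpG arrays as on the others is not given in the sources used here, and each gene's A151 plus CpG value rests on it.

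**Figure D3:**
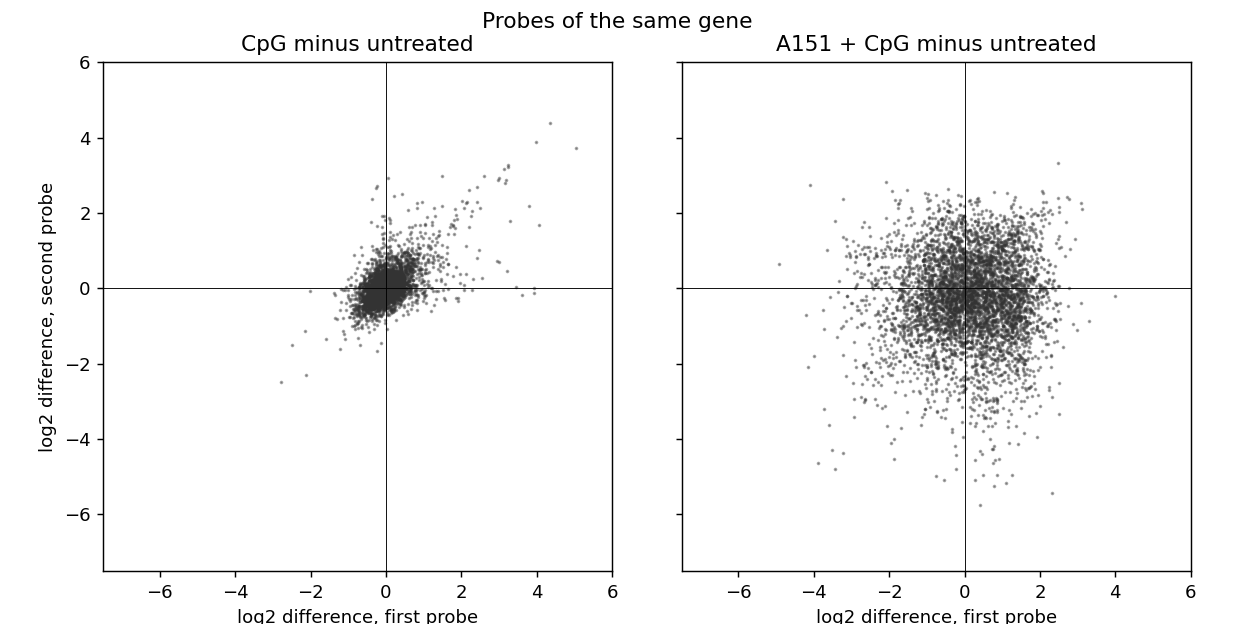
Log2 difference of the first against the second probe of 4899 genes, for CpG minus untreated (left) and A151 plus CpG minus untreated (right); each point is 1 gene. The points on the left follow the diagonal with a correlation of 0.578 and those on the right do not (0.037).

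Other strong increases against untreated on the A151 plus CpG arrays were Serpina3f (4.27 ± 0.33), Csta2 (3.89 ± 0.29), Rasl11b (3.72 ± 0.17), Chil1 (3.39 ± 0.19) and Fkbp5 (3.36 ± 0.15), and other strong decreases were Trf (-4.99 ± 0.27) and Iglv1 (-4.77 ± 0.25). Chemokines had 14 of 25 members higher, among them Cxcl1 (2.59 ± 0.15) and Cxcl2 (2.57 ± 0.18), and Cxcl16 and Ccl19 lower (camera adjusted p = 0.0152, and adjusted p = 0.367 with an estimated correlation). Immediate early genes had 16 of 24 higher, such as Dusp1 (2.21 ± 0.20) and Fos (1.90 ± 0.16), and Nr4a2 and Klf6 lower (adjusted p = 0.0171, and adjusted p = 0.56 with an estimated correlation). Type I interferon-stimulated genes had 29 of 48 higher and 8 lower (adjusted p = 0.0227, and adjusted p = 0.56 with an estimated correlation), and this call was lost after quantile normalization (0.247) and scaling (0.63). Cell cycle genes had 22 of 34 lower, such as Mcm3 (-3.51 ± 0.20), Top2a (-3.18 ± 0.26) and Mki67 (-2.93 ± 0.38), and Aurka, Bub1, Mcm5 and Kif11 higher (adjusted p = 0.0109, and adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone, the counts were 14 higher for chemokines, 16 for immediate early genes and 29 for interferon-stimulated genes, and 23 lower for cell cycle. The other 25 lists had adjusted p values from 0.056 to 0.801. After quantile normalization, MHC class I (mean -0.84, adjusted p = 0.0297), MHC class II (-1.12, 0.00289), B cell (-1.05, 0.00289), T cell (-0.55, 0.0285) and erythroid lists (-0.81, 0.0297) passed as lower. After scaling to one spread these stood at -0.85, -1.74, -1.77, -0.74 and -1.61 (adjusted p from 4.77e-08 to 0.011). NK cell (-0.85, 0.011), monocyte (-1.21, 0.00336) and platelet lists (-0.67, 0.0351) then also passed as lower and glycolysis (0.73, 0.0122) as higher. With a single factor per array, this scaling by itself lowers genes with high ratios on the A151 plus CpG arrays, so these values are no separate check. Of the 25 lists as deposited, negative feedback regulators passed without A151 plus CpG replicate 1 or 2 (0.0411 and 0.0461) or untreated replicate 2 or 4 (0.0469 and 0.0402), and dendritic cell markers without A151 plus CpG replicate 1 (0.0411) or untreated replicate 2 (0.0469). For MHC class I presentation the median was 0.01 and the mean -0.65. Medians and means also differed in sign for co-stimulation, monocyte and erythroid lists. The lower members Cxcl16, Ccl19, Nr4a2 and Klf6 and the higher members Aurka, Bub1, Mcm5 and Kif11 were named after their values were seen. Cxcl16 had no call without untreated replicate 1, 2, 5 or 6 or A151 plus CpG replicate 1, 2 or 3 (adjusted p from 0.0588 to 0.0983), with array weights (0.0639) or with a running median along probe numbers (0.13). Mcm5 had none without A151 plus CpG replicate 1 or 3 (0.0614 and 0.0584), after quantile normalization (0.114), after scaling (0.102) or with the running median (0.0527).

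Several immune genes followed in every comparison depended on how the arrays were scaled. Myd88 (2.71 ± 0.14), Tnfaip3 (2.49 ± 0.15), Nfkbia (1.42 ± 0.20), Socs1 (1.30 ± 0.16) and Il10 (0.81 ± 0.23) were higher than in untreated spleen and Irf7 was lower (-1.35 ± 0.22). Ccl2 was at -0.16 ± 0.14 (adjusted p = 0.307) and turned to 0.40 after quantile normalization and 0.57 after scaling to one spread. Il1b was higher by 0.72 ± 0.20 as deposited, at -0.01 after quantile normalization and at -1.20 after scaling. Ifng was higher by 0.83 ± 0.15, but at 0.23 with no call after quantile normalization (adjusted p = 0.156) and at -0.21 after scaling. Il1rn was higher by 0.39 ± 0.16 (adjusted p = 0.034), but at -0.13 after quantile normalization and -0.12 after scaling, and its probes were at -0.30 and 1.09. Its call was lost without A151 plus CpG replicate 1 or 2 (0.0535 and 0.144) or without untreated replicate 1, 3 or 6 (0.0507, 0.0742 and 0.0573). Tlr9 was lower (-0.48 ± 0.16, adjusted p = 0.0131), with no call without A151 plus CpG replicate 3 (0.0608) or with a running median along probe numbers, which moved it to -0.04 (0.793).

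On the A151 plus CpG arrays, 37 of 48 type I interferon-stimulated genes were lower than on the CpG arrays and 3 were higher (camera adjusted p = 7.01e-10, and adjusted p = 0.122 with an estimated correlation). The treatment and the labelling batch cannot be told apart in this comparison. Ifit3 was at -4.87 ± 0.23, with 3 of 3 probes lower (-6.60 to -1.59), Phf11d was at -4.66 ± 0.17, Ifit2 at -3.93 ± 0.21, Slfn2 at -3.96 ± 0.37, Ifi35 at -3.19 ± 0.20 and Usp18 at -3.15 ± 0.26. The chemokines Ccl3, Ccl4 and Cxcl11 were at -3.36 ± 0.22, -2.47 ± 0.14 and -2.25 ± 0.23, whereas Cxcl10 was at -0.62 ± 0.22. Tnf was at -1.97 ± 0.29 and Il6 at -1.29 ± 0.29. Lgals9 (-3.59 ± 0.18), Irf1 (-2.53 ± 0.20) and Jak2 (-2.44 ± 0.13) were lower with 3 of 3, 4 of 4 and 3 of 3 probes in that direction, and Cd69 (-2.79 ± 0.26), Fas (-2.57 ± 0.16) and Casp4 (-2.33 ± 0.22) with 2 of 2. The probes of Lgals9 ran from -5.14 to -1.01 and those of Cd69 from -4.91 to -0.66. Most genes named in this comparison had a single probe. Of 4899 genes with 2 to 5 probes, 566 had all probes called lower and 415 all called higher, while 1163 had all probes called but in opposed directions. In limma's test, 9583 genes differed between these groups, 4997 higher and 4586 lower on the A151 plus CpG arrays, and 4684 of them reached 2-fold. The call of Cxcl10 (adjusted p = 0.0191) was lost without CpG replicate 2 (0.0635) or A151 plus CpG replicate 3 (0.0711) and with array weights (0.0626).

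The type I interferon-stimulated genes that were higher than with CpG alone were Mx2 (0.82 ± 0.16), Trim21 (0.57 ± 0.17) and Uba7 (1.19 ± 0.33). Interferon gamma-inducible GTPases and regulators had 15 of 21 lower and Igtp higher (adjusted p = 0.0138, and adjusted p = 0.117 with an estimated correlation). MHC class I presentation, with immunoproteasome and transporter genes, had 9 of 17 lower, such as Psme2 (-3.78 ± 0.21), H2-Q7 (-3.15 ± 0.21) and H2-T23 (-2.91 ± 0.19), and H2-K1 and Psmb9 higher (adjusted p = 0.0386, and adjusted p = 0.619 with an estimated correlation). Cell cycle genes had 18 of 34 lower, such as Mcm3 (-3.61 ± 0.21) and Ccnd2 (-3.11 ± 0.23), and 6 higher (adjusted p = 0.0386, and adjusted p = 0.759 with an estimated correlation). Adjusted over the list alone, 37, 15, 9 and 18 members of the interferon, interferon gamma, MHC class I and cell cycle lists were lower. Without A151 plus CpG replicate 2 the MHC class I list (0.0516) and the cell cycle list (0.108) lost their calls, as did the cell cycle list without CpG replicate 1 (0.0899) or 2 (0.0553), after quantile normalization (0.0938) and after scaling (0.146). The other 25 lists had adjusted p values from 0.0714 to 0.948, with medians and means of opposite sign for glycolysis, NK cell, erythroid and platelet lists. After quantile normalization, NF-kappaB (mean -0.80, adjusted p = 0.00709), co-stimulation (-0.73, 0.0079), apoptosis (-0.70, 0.0073) and MHC class II lists (-0.75, 0.037) passed as lower. After scaling to one spread 21 lists passed, among them B cell (-1.71, adjusted p = 2.93e-07), MHC class II (-1.69, 3.24e-05), erythroid (-1.57, 1.41e-05), NF-kappaB (-1.38, 2.06e-06), co-stimulation (-1.37, 3.15e-06) and apoptosis (-0.88, 0.00124) as lower. Glycolysis (0.59, 0.0313) and oxidative phosphorylation (0.27, 0.0221) then passed as higher. Here too the scaling by itself lowers high ratios on the A151 plus CpG arrays, so these values are no separate check. The higher members Mx2, Trim21, Uba7, Igtp, H2-K1 and Psmb9 were named here after their values were seen, and scaling the arrays to one spread turned Mx2 to -1.13, Igtp to -1.53, Psmb9 to -0.99 and H2-K1 to -0.31. It also ended the calls of Trim21 (adjusted p = 0.2) and Uba7 (0.243), and after quantile normalization Trim21, Uba7, Igtp, H2-K1 and Psmb9 had no call (0.227, 0.0879, 0.358, 0.455 and 0.207).

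Many immune genes were not lower on the A151 plus CpG arrays than on the CpG arrays. In limma's test, 10 of 25 chemokines were lower and 5 higher, and 12 of 30 cytokines were lower and 6 higher. Of the negative feedback regulators, 11 of 24 were lower and 6 higher. Among all 14947 genes tested, 4586 were lower and 4997 higher. The camera adjusted p was 0.305 for chemokines, 0.452 for cytokines and 0.393 for negative feedback regulators, so these lists did not stand out from other genes. Socs3 was higher than with CpG alone by 1.53 ± 0.23, Il12a, a subunit of interleukin 12, by 1.91 ± 0.17 with 2 of 2 probes, and Ifng by 0.79 ± 0.16, which turned to -0.31 after scaling to one spread. Myd88 was higher by 1.29 ± 0.16, and at 0.13 with no call after scaling (adjusted p = 0.547). Nfkbia (0.03 ± 0.21, adjusted p = 0.903) and Tnfaip3 (0.07 ± 0.16, adjusted p = 0.728) had no call as deposited, stood at -0.40 and -0.29 after quantile normalization and were lower at -0.86 and -1.22 after scaling. Il1b was at -0.42 ± 0.22 (adjusted p = 0.102) and passed without CpG replicate 2 (0.00743) or A151 plus CpG replicate 4 (0.0481), after quantile normalization (0.0125), after scaling (1.23e-07) and with a running median along probe numbers (0.0462). Genes that CpG had lowered were among the strongest increases, with Tcf21 at 3.66 ± 0.30, Gpd1 at 3.59 ± 0.22, Arvcf at 3.40 ± 0.23, Id4 at 3.18 ± 0.27, Cmbl at 3.13 ± 0.21 and Slc40a1 at 3.06 ± 0.19. Cbx7 (3.54 ± 0.21) and Per3 (3.37 ± 0.15), a clock gene, were also higher. Spi1 (-5.82 ± 0.22), Rpl7a (-5.67 ± 0.20), Ighv2-3 (-5.58 ± 0.29, with 3 CpG arrays) and Unc93b1 (-4.70 ± 0.24), which carries TLR9 to endosomes, were among the 12 largest decreases. Ccl2 (-1.32 ± 0.15), Il1rn (-1.22 ± 0.17), Il10 (-0.83 ± 0.26), Socs1 (-0.67 ± 0.18), Irf7 (-2.14 ± 0.25) and Tlr9 (-1.26 ± 0.17) were lower. The probes of Socs1 stood at 0.26 and -1.59 and those of Il1rn at -0.21 and -2.22.

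Scores over whole lists, the mean over the genes of a list of each array's difference from the untreated mean, described the groups without choosing genes. The type I interferon score was 2.06 ± 0.126 (SD, n = 4) with CpG and 0.623 ± 0.12 with A151 plus CpG, against 0 ± 0.097 in 6 untreated arrays. The interferon gamma-inducible score was 1.589 ± 0.032 and 0.698 ± 0.092, the chemokine score 1.498 ± 0.109 and 1.089 ± 0.067, and the NF-kappaB score 1.294 ± 0.085 and 0.743 ± 0.176. Each of these 4 scores was lower with A151 plus CpG than with CpG in a 2-sided exact permutation test (p = 0.0286, adjusted 0.046 over 29 lists, the smallest p that 4 against 4 arrays allow). Lists outside the immune response were lower at the same p, such as ribosomal proteins (-0.312), heat shock and unfolded protein response (-0.486) and cell cycle (-0.716). The A151 plus CpG arrays stood apart from the others as a set, so this p does not single out the immune lists. The immediate early score (0.736 ± 0.119 against 0.407 ± 0.065 with CpG), the dendritic cell score (0.804 ± 0.135 against 0.312 ± 0.103) and the stromal, endothelial and adipose score (0.317 ± 0.202 against 0.003 ± 0.083) were higher at the same p. The last pair had no call after quantile normalization (differences of 0.210 and 0.291, adjusted p = 0.0663), and the dendritic cell list turned to -0.36 after scaling. With the median over each list, 0 of 29 lists passed this test after adjustment and 14 had an unadjusted p under 0.05. The difference was then -1.286 for the type I interferon, -0.967 for the interferon gamma-inducible and -0.463 for the NF-kappaB list (adjusted p = 0.0592 at the smallest exact p), but -0.068 for chemokines (0.497). The neutrophil score was 0.828 ± 0.158 with CpG and 0.879 ± 0.052 with A151 plus CpG (exact p = 0.6), a difference that turned to -0.252 after quantile normalization, with a call (adjusted p = 0.036). The T cell score was -0.124 ± 0.138 and -0.132 ± 0.048 (exact p = 0.914), a difference of -0.008 that became -0.294 after quantile normalization, with a call (adjusted p = 0.036). The B cell score was -0.129 ± 0.081 and -0.502 ± 0.08 (exact p = 0.0286).

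**Figure D4:**
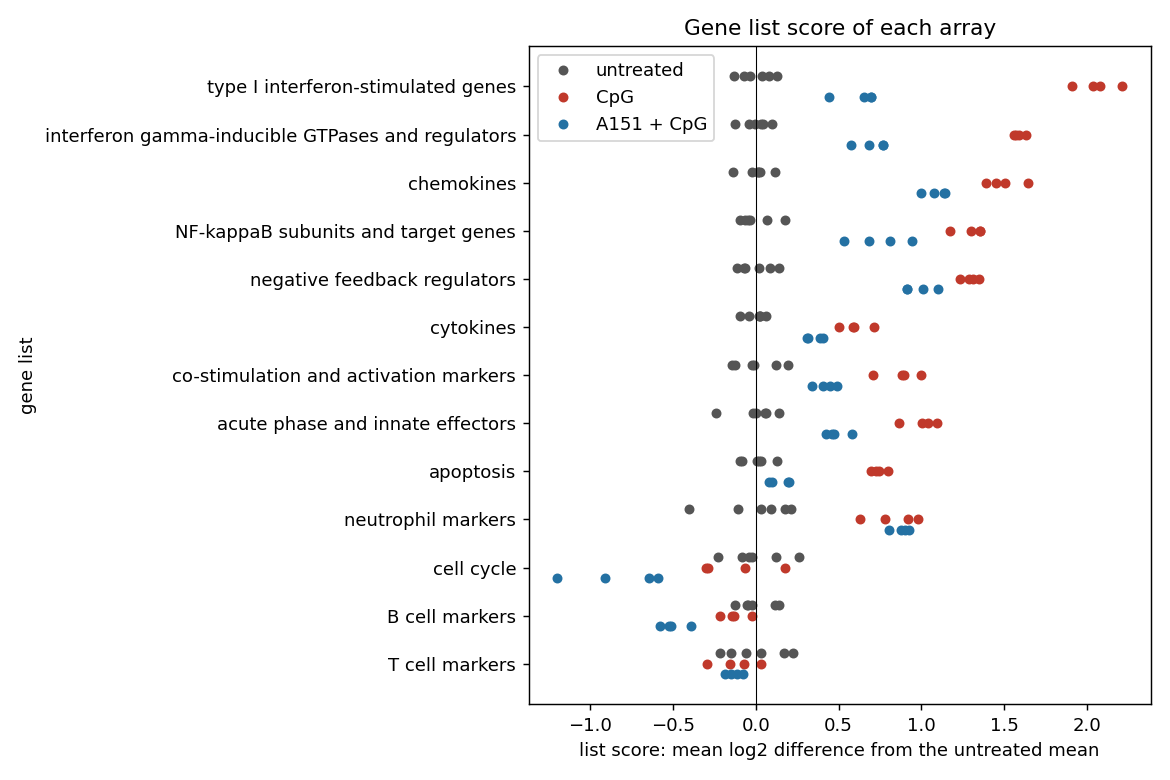
List score of each array, the mean log2 difference from the untreated mean over the genes of a list, for 13 lists; each point is 1 array. The type I interferon scores have means of 2.06 in the CpG group and 0.623 in the A151 plus CpG group, and the neutrophil scores of 0.828 and 0.879, in the opposite order after quantile normalization.

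The 461 genes that CpG raised 2-fold or more stood on average at about 49.4% of the CpG response on the A151 plus CpG arrays, where A151 and the labelling batch cannot be told apart. Of all 14947 genes tested, 4586 were lower with A151 plus CpG than with CpG and 4997 were higher. Of the 461 raised genes, 281 (61%) were lower with A151 plus CpG than with CpG and 66 were higher, while 280 stayed above untreated and 62 fell below it. Their mean difference from untreated was 1.76 with CpG and 0.87 with A151 plus CpG, and the retained share was 49.4% ± 0.6 (SD, n = 4 A151 plus CpG arrays). This SD holds the CpG and untreated means fixed and leaves out their spread. Without CpG replicate 2 the share was 44.7%. With genes chosen on other CpG and untreated arrays than those measured, the pooled share was 50.2% (46.9 to 55.1 over 12 fits). The level that a gene without a CpG change had on the A151 plus CpG arrays gave a calibrated share of 45.8% (95% bootstrap interval over genes 39.7 to 52.4), and single genes scattered around that level with an SD of 0.96. Of 64 genes with both probes induced, both probes were lower than with CpG in 47 and higher in 6, where the probes had been chosen as high on the CpG arrays. For 43 of them at least 5 genes without a CpG change had similar CpG levels in both probes, and the mean difference from CpG was -1.24, against -0.17 (95% range -0.49 to 0.13 over 20000 draws) in such matched genes. Against untreated, the first and second probes of 73 genes that CpG changed 2-fold had a correlation of 0.191 on the A151 plus CpG arrays, and 29 of 51 pairs with both probes called had the same sign (56.9%, 95% exact binomial interval 42.2 to 70.7). Scaling the arrays to one spread moved the share to 24.3%, with 444 genes lower.

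**Figure D5:**
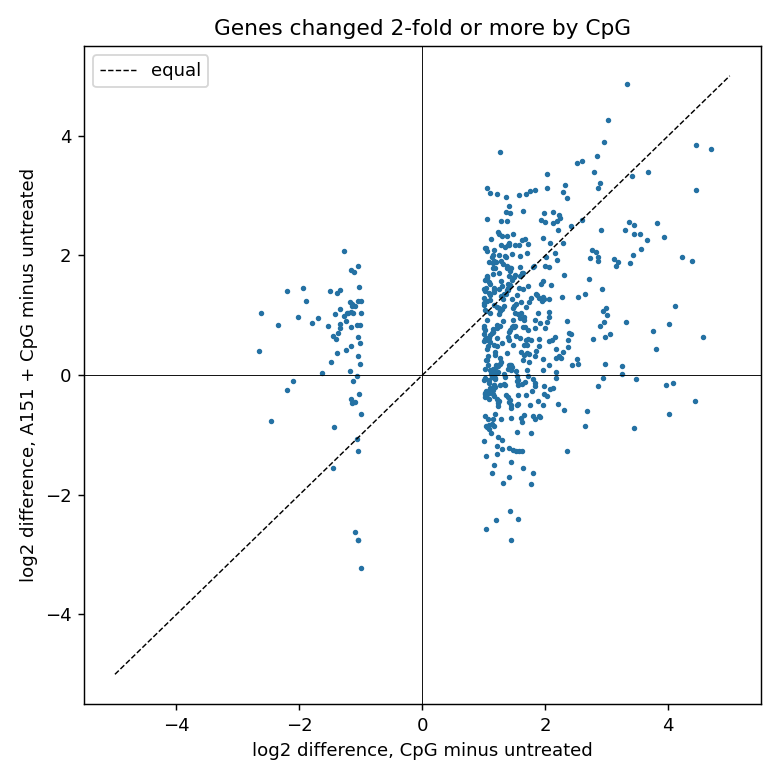
Log2 difference from untreated in A151 plus CpG spleen against that in CpG spleen for the 530 genes that CpG changed 2-fold or more; each point is 1 gene and the dashed line marks equal values. The 461 raised genes average 1.76 on the horizontal and 0.87 on the vertical axis.

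The 69 genes that CpG lowered 2-fold or more, Slc40a1, Tcf21, Gpd1 and Id4 among them, were mostly higher on the A151 plus CpG arrays. Of all 14947 genes tested, 4997 were higher with A151 plus CpG than with CpG and 4586 were lower. Of the 69 lowered genes, 62 were higher with A151 plus CpG than with CpG, 45 stood above untreated and 13 below it. Their mean difference from untreated was -1.36 with CpG and 0.42 with A151 plus CpG. The retained share was -30.9% ± 15.6 (SD, n = 4 A151 plus CpG arrays, with the other means held fixed). It turned to 6.0% after quantile normalization and 9.9% after scaling. The calibrated share was -27.0% (95% bootstrap interval -49.4 to -3.5), and the pooled share with genes chosen on other arrays was -38.6%, with single fits from -1116.8% to -10.6%, so that its size is not settled. No test with both probes of a gene or with genes of similar CpG level was made for this set, and differences of single probes or of the batch stay open.

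A set of 7472 genes (50% of those tested) stood apart on the A151 plus CpG arrays from both other groups without a call between CpG and untreated, 3885 higher and 3587 lower. The highest against untreated were Sdr42e1 (3.34 ± 0.33), Med26 (3.14 ± 0.17), Dnase1l3 (3.01 ± 0.23), Fam167a (3.00 ± 0.19) and Per3 (2.97 ± 0.14), of which Dnase1l3 had no call after scaling (0.52, adjusted p = 0.185). The lowest were Spi1, Rpl7a, Ighv2-3, H4c4 and Gpx1. Where a first probe stood apart in this way, the second probe of the gene had the same sign in 1323 of 2700 genes (49%, 95% exact binomial interval 47.1 to 50.9).

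The comparisons of both treatments with untreated shared 642 genes called higher, with Cxcl10, Ccl12, Socs3 and Il6 among them, and 172 called lower, and 529 genes were called in opposite directions. Independent lists of these sizes would share 407.6 and 189.9, with 572.5 opposite. Across genes the log2 differences had a correlation of 0.143 and a covariance of 0.0669, against 0.404 and 0.0147 on average in 100 simulations of unchanged groups against the same untreated arrays. With the untreated arrays split between the comparisons, 483 and 565 genes were called in the same direction, with correlations of 0.075 and 0.144.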

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

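The test of histone genes for priming was written down before its result was seen and the choice of genes on other arrays was planned, while the other tests of an explanation here were chosen after the result was seen. The first pattern is that the A151 plus CpG arrays differed from the others in most genes. A gene-level difference, from A151, other mice or another lot of reference RNA, would move the probes of a gene together, and is excluded as the whole cause by the 48.8% of 2463 genes with both probes called that had the same sign. Scaling to one spread left 8993 genes called, of which 7838 were called in the same direction as before. That count cannot decide on the wider spread of these arrays, since a single factor per array also creates differences for genes far from 0. A plain stretch of all values is excluded as the whole cause, because it would leave correlations between arrays unchanged. The mean correlation with untreated arrays was 0.554, against 0.845 for CpG. A difference of single probes between the array sets may underlie much of the pattern, consistent with the correlation of 0.037 between probes of a gene. Another print of these arrays, or another order of part of the probes, could be its source and stays open. The correlation with untreated along the probe numbers was 0.50 to 0.68 in 31 windows of 1000 probes (0.87 to 0.98 for CpG). Another order of all probes would leave little correlation in any window, so these values argue against it.

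The second pattern is that CpG-induced genes were lower on the A151 plus CpG arrays than on the CpG arrays. The choice of genes on the same CpG arrays is excluded as the whole cause by the retained share of 50.2% with genes chosen on other arrays (46.9 to 55.1). Weaker ratios for all genes are excluded as the whole cause by the calibrated share of 45.8% (39.7 to 52.4). Single-probe differences that strike induced and other genes alike are excluded as the whole cause for 43 genes with both probes induced, whose mean difference of -1.24 lay below the range of -0.49 to 0.13 in genes of similar CpG level without a CpG change, while 21 genes had no match and such differences may still make up part of the decrease. A151 itself cannot be told apart from another cohort of mice, CpG preparation or labelling batch, because 0 arrays of other groups lie in the range of experiment numbers of the A151 plus CpG arrays.

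The third pattern is that replication-dependent histone genes, whose RNAs lack a poly(A) tail, were among the lowest on the A151 plus CpG arrays. Less priming of such RNAs could lower them, although per the labels both channels of an array had the same primer. Without the 4 seen first, 48 histone genes had a mean difference from CpG of -0.90 (random lists -0.29 to 0.31), with 25 called lower and 7 higher and a permutation p = 5e-05, the smallest the resampling can give (adjusted 2e-04). Fewer cells in S phase could lower them too, and 12 S phase genes had a mean of -0.77 (random lists -0.61 to 0.60, permutation p = 0.012, adjusted 0.024), but these 12 are members of the cell cycle list, whose lower values had been seen. Some of the 48, such as H4c12 (-3.92) and H2ac15 (-4.31), belong to the same histone families as the 4 seen first. Random lists take genes as independent, which genes of 1 family or 1 phase need not be. The cell cycle list had an estimated correlation of 0.366 between genes, so both permutation p-values may be too small. Both explanations stay open, and in CpG against untreated 47 of the 48 histone genes were also below 0, with a mean of -0.41 and 12 called.

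Of 100 splits of the arrays drawn for CpG against untreated, 1, the real one, gave as many as 1768 genes (highest other 82), and for A151 plus CpG against untreated 1 of 100 gave as many as 9892 (highest other 4816, from a split that kept the 4 A151 plus CpG arrays together). For A151 plus CpG against CpG, 1 of 35 splits gave as many as 9583 (highest other 3). Splits that mix the groups widen the spread and remove calls, so these 3 counts show that the array sets differ beyond chance. They do not show it for single genes, and a batch effect cannot be excluded for the 2 A151 plus CpG counts. For the number of lists called, 36 of 100, 29 of 100 and 15 of 35 splits gave as many as 12, 4 and 4 lists (highest other 18, 11 and 8). Many of these splits still carry part of the treatment difference, and the 18 lists came from a split that kept the 4 CpG arrays together. The splits therefore cannot decide whether these list counts exceed chance. Of 70 assignments of the treated arrays to the 2 treatments, 2 gave as many as 281 induced genes lower and 2 as many as 62 repressed genes higher, in each case the real one and the plain exchange of labels. The exchange gave 2293 of 2484 and 1968 of 1999 genes, against 281 of 461 and 62 of 69 in the real assignment, and mixed assignments gave at most 3 and 0. For the genes set apart, 1 of 70 gave as many as 7472 (highest other 384), and for the overlap 2 of 70 gave 814, of which 1 was the exchange, with 438 the highest mixed value. Mixed assignments join arrays of both treatments in the same group, which widens the spread and removes calls. The low mixed counts therefore show that the treated array sets differ. They cannot decide whether CpG-changed genes moved more than others or whether the overlap exceeds that of unrelated lists. A batch effect cannot be excluded for any of these 4 counts.

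Single arrays stood far from the others of their group, by Dixon's gap over range, in 1 of 9 groups of array quality values, 1 of 87 of list scores and 15 of 364 of named genes, where chance gives about 1 in 20. Untreated replicate 5 lacked values for 2009 probes, against 209 to 777 on the others. Untreated replicate 6 had a stromal, endothelial and adipose score of -0.137 (others -0.003 to 0.074). Among untreated arrays, Ifit2 was at 0.094 in replicate 1 (others -0.741 to -0.448), and in replicate 2 Nfkbiz was at -1.774 (others -1.307 to -1.027) and Mcl1 at 0.759 (others 1.125 to 1.241). In CpG replicate 1, Ifi204 was at 2.230 (others 2.589 to 2.649), Gbp2 at 4.5 (others 4.778 to 4.828) and Trim21 at 0.630 (others 0.174 to 0.231). In CpG replicate 2, Il1rn was at 2.130 (others 2.672 to 2.765), Myc at 1.048 (others 0.742 to 0.771) and Csta2 at 5.725 (others 4.729 to 4.872). Id4 was at 0.188 in CpG replicate 3 (others -0.232 to -0.162), and in CpG replicate 4 Cd274 was at 3.479 (others 2.732 to 2.837) and Casp4 at 2.606 (others 2.764 to 2.796). On the A151 plus CpG arrays, Iigp1 was at 6.130 in replicate 2 (others 3.029 to 3.328), and in replicate 4 Impg2 was at -1.094 (others -2.149 to -2.064) and Cxcl16 at 0.289 (others -0.156 to -0.103). Among 6749 probes without a gene name, 380 were called in CpG against untreated, 252 higher and 128 lower.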

How the results depend on the processing

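Scaling the arrays to one spread, the running median along probe numbers, the demand that all probes of a gene be called and the calibration were tests chosen after the results were seen, and the other alternatives were planned. For CpG against untreated, the count of 1768 genes was 2703 with probes in place of genes, 1107 at an adjusted p under 0.01, 530 with a 2-fold minimum, 193 with all 2 to 5 probes of a gene called in one direction, 582 with the range of experiment numbers as a block and 465 within the range that holds both groups, and the last 2 counts rest on the same 1 untreated array. The repeat number as a block gave 1152 genes, but the numbers were not taken to pair the samples. The deviations of CpG and untreated arrays of one number correlated at 0.13, 0.05, 0.42 and -0.10, and 2 of 4 CpG arrays correlated best with the untreated array of their own number. With this block the oxidative phosphorylation (-0.13, adjusted p = 0.0227) and T cell lists (-0.21, 0.0174) passed as lower, and fry, which does not compare a list with other genes, called the TLR9 (0.000309), glycolysis (0.0118) and dendritic cell lists (0.00013). For A151 plus CpG against untreated (9892 genes) the count was 19558 with probes, 4483 with a 2-fold minimum and 969 with all probes called, and against CpG (9583 genes) 18836, 4684 and 981. Leaving out 1 array gave 1362 to 1670, 9353 to 9788 and 9084 to 9639 genes in the 3 comparisons. The retained share of induced genes (49.4%) was 41.2% after quantile normalization, 24.3% after scaling, 38.7% with probes, 53.6% over all called genes, 50.2% with genes chosen on other arrays and 45.8% calibrated, and 44.7% to 50.6% with 1 array left out. The count of induced genes lower on the A151 plus CpG arrays (281) was 444 after scaling, 528 with probes, 603 over all called genes and 265 to 303 with 1 array left out. The retained share of repressed genes (-30.9%) turned to 6.0% after quantile normalization and 9.9% after scaling and was -37.7% to -17.9% with 1 array left out, and their count (62) was 103 with probes, 433 over all called genes and 56 to 70 with 1 array left out. Genes set apart (7472) numbered 3281 with a 2-fold minimum in both comparisons and 7047 to 7529 with 1 array left out. The overlap of 814 genes was 483 in 1 split of the untreated arrays between the comparisons and 565 in the other. Of the list tests, A151 plus CpG against untreated (4 lists) gave 0 with an estimated correlation in camera (3 at an unadjusted p under 0.05), 21 with fry, 8 after quantile normalization, 12 after scaling and 4 to 6 with 1 array left out. A151 plus CpG against CpG (4 lists) gave 0 (3 unadjusted), 21, 7 and 21 in the same order and 2 to 4 with 1 array left out, the 2 without A151 plus CpG replicate 2. CpG against untreated (12 lists) gave 12 to 17 with 1 array left out. Of 18 list scores called between A151 plus CpG and CpG by the exact permutation test, 0 passed with the median over the list, where 14 of 29 lists had an unadjusted p under 0.05. Scaling turned the means of the platelet list against untreated (-0.67) and against CpG (-0.80) and of the neutrophil list against CpG (-1.14). Quantile normalization turned the scores of the TLR9 (-0.131), NK cell (-0.421) and platelet lists (-0.284) against untreated and of the neutrophil list (-0.252) against CpG. Against untreated, scaling turned P2ry12 (-0.63), Il1b (-1.20) and Ccl2 (0.57, and 0.40 after quantile normalization). Against CpG it turned Fcmr (-0.69), Cd3d (-0.99), Nfkbia (-0.86), Tnfaip3 (-1.22), Mx2 (-1.13), Igtp (-1.53) and Psmb9 (-0.99). P2ry12, Fcmr and Cd3d are named here because they turned. Over the named genes and alternatives, 1945 values kept their call and its direction, or had no call in either fit, and 87 lost the call for CpG against untreated. The counts were 2809 and 48 for A151 plus CpG against untreated, and 2527 and 33 for A151 plus CpG against CpG. Values without a call in either fit count as kept even where the sign turned, as for Ifng in CpG against untreated. Where the construction of an alternative does not show it, the cause was not tested. Signal over background was not analysed here, so its limit on weak probes is unknown.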

Other observations

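The tests of the clock and glucocorticoid lists were written down before their result was seen, and the tests of the retained share by list were chosen after it was seen. Per3 and Fkbp5 were among the highest genes on the A151 plus CpG arrays, and a different time of day or more glucocorticoid in those mice could raise them. Over 13 clock genes, with signs turned to the expected direction, the mean difference between A151 plus CpG and CpG was -0.36 (random lists -0.59 to 0.57, permutation p = 0.22, adjusted 0.24), opposite to a shift in the direction of Per3. Over 7 glucocorticoid-induced genes it was -0.47 (random lists -0.82 to 0.75, permutation p = 0.24, adjusted 0.24), with 0 called higher and 5 called lower. Neither list moved with the genes that prompted the test. The same glucocorticoid genes had a mean of 0.66 in CpG against untreated spleen (permutation p = 0.0051, not adjusted), with 7 of 7 above 0. Random lists take genes as independent here too, so this p may be too small.

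Whether lists of induced genes kept different shares of their CpG response was left undecided by the permutation tests. The 40 induced type I interferon-stimulated genes kept a calibrated 30.4% and the other induced genes 48.0% (permutation p = 0.15, adjusted 0.77). The 6 induced neutrophil markers kept 104.4% against 44.8% (permutation p = 0.053, adjusted 0.58). After quantile normalization the score of the whole neutrophil list was lower than with CpG (-0.252), so this share depends on how the arrays are scaled. The share was 15.7% for 7 apoptosis genes, 51.5% for 5 immediate early genes, 53.5% for 9 cytokines, 54.7% for 14 interferon gamma-inducible genes, 56.1% for 13 acute phase and innate effector genes, 58.1% for 13 NF-kappaB genes, 59.2% for 12 chemokines, 63.6% for 12 negative feedback regulators and 83.0% for 6 co-stimulation and activation markers, with adjusted p values from 0.77 to 0.87 for these 9 lists.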
